A study of Mus musculus with 12 samples.

How the data were processed

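Gene expression had been measured on 12 Affymetrix arrays of sorted mouse back skin cells, with HG, bulge and total keratinocyte fractions of 2 genotypes in 2 sets. Per the labels, cells were sorted by Rosa26-YFP, P-cadherin and CD34, RNA was taken in Trizol, and biotin-labelled cRNA was made from 2 µg of total RNA. The deposited values are MAS5 signal, in intensity units on a linear scale, with 1 column per array. MAS5 is named per the submitters' processing notes and its version is not given in the sources used here. The authors scaled each array to a mean of 500 after trimming 2% of probe sets at each end, which was checked in the values of all 12 arrays. No further normalization was added. No detection calls were used here.

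Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 had none in the table used. Symbols were looked up by gene ID for 34741 probe sets, and older ones were replaced. Per gene the probe set with 1 symbol and the highest mean log2 signal over the 12 arrays was kept, which gave 18193 genes. Values below the pooled 25th percentile of all arrays (20.7) were set to it before the log2, so a difference from a value at this floor (4.37 on the log2 scale) is a lower bound. Genes were tested if their signal exceeded the pooled median (84.7) on at least 2 arrays of the fit. Precision is limited by the number of arrays.

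Comparisons between groups used limma 3.58.1 on R 4.3.3 (lmFit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. HG and bulge were compared with the genotype-by-set condition as a block of 4 levels. HFSCs, as the mean of HG and bulge, were compared with total keratinocytes in the same way on 12 arrays. The genotypes were compared on 12 arrays with the fraction-by-set cell as a block, and in total keratinocytes without a block. Set effects within each genotype, their interaction and the genotype effect within each set came from 1 fit of the 8 HG and bulge arrays, with fraction as a term. There HG and bulge were the observations of a condition, so the spread is that between fractions. The labels do not say whether fractions of a set came from the same mice. HG arrays of 1 genotype were compared between sets by counting genes changed at least 2-fold with the higher array above the pooled median, without a test. Pairs of total keratinocyte arrays gave such counts between arrays of 1 group, although these also differ in set.

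The design, the comparisons, 26 gene lists and the alternatives were chosen before the data were examined, apart from those named as later additions. Lists of 342 genes, of which 325 were measured, covered the TGF-beta and BMP pathways, bulge, hair germ, Wnt, Hedgehog, cell cycle and CDK inhibitor genes, epidermal, basal, infundibular, sebaceous, hair shaft and wound keratinocyte genes, dissociation stress genes, markers of dermal papilla, fibroblasts, melanocytes, immune, endothelial, muscle, erythroid and Schwann cells, and a sex check. List genes without a usable probe set were not analysed here. Lists were tested with fry and with camera (preset correlation 0.01, and estimated correlation), adjusted over the lists of a comparison. Fry tests whether a list moves on balance in 1 direction and camera compares it with all other genes.

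Genes were named by a fixed rule. Tgfbr2 and the sort markers Cdh3 and Cd34 were given on every array, and Tmeff1, Id1, Id2, Id3 and Mki67 in the genotype and set comparisons. Each tested comparison gave the 6 genes of largest change in each direction among those past the threshold with the same sign in every pair of arrays, and each comparison of single arrays the 6 highest and 6 lowest. Of each list described up to 4 members with the largest change were named, and others where a count needed them.

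The alternatives were quantile normalization, no floor, a floor at the pooled median, no filter, a filter at the pooled 75th percentile (474), the mean of all probe sets of a gene, eBayes without trend, a 2-fold minimum, other blocks, all 12 arrays for the set contrasts, and leaving out each array or pair in turn. Further ones, which left out arrays in doubt or the sort markers from the lists, were added after the values were seen. The fits were tested on simulated data with the same spread and independent arrays, in which they recovered between 2.99% (the interaction) and 71.6% (cKO against Het over all fractions) of 2-fold changes, and between 61.2% and 100% of 4-fold changes.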

Results

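Gene expression was measured on 12 Affymetrix arrays of 45101 probe sets, each hybridized with labelled cRNA from epithelial cells sorted from mouse back skin. The female mice were 72 to 74 days old, on a mixed C57BL/6 and CD1 background, at the second telogen-to-anagen transition, when resting hair follicles enter a new growth phase. Het and cKO are the labels' names for the 2 genotypes at the type II TGF-beta receptor gene Tgfbr2, a control and a conditional knockout. Each genotype gave 3 fractions, which were hair germ (HG) cells, bulge cells and total keratinocytes. HG and bulge cells are both hair follicle stem cells (HFSCs). Each fraction was collected in 2 sets. The labels call HG and bulge cells of set 1 quiescent in both genotypes. In set 2 the labels call the Het cells activated and the cKO cells aberrantly quiescent. The arrays made 10 groups, of which 8 held 1 array and the total keratinocytes of each genotype held 2. Median signal per array lay between 63.9 and 109. The number of arrays limits the precision of every value, and the p-values measure the spread between these arrays and not between mice.

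Tgfbr2, the targeted gene, could not serve as a check on the genotype labels, because the position of its probes relative to the deleted part of the gene is not given in the sources used here. The probe set with the highest mean signal gave log2 signals of 11.48 in Het HG, 12.39 in Het bulge and 11.96 in Het total keratinocytes of set 1. The cKO values of set 1 were 12.02, 12.14 and 12.09 in the same order. In set 2 they were 10.35, 11.92 and 11.68 in Het and 11.31, 11.89 and 11.78 in cKO. Across all fractions the limma difference between cKO and Het was 0.24 (adjusted p = 0.67), with cKO higher in 4 of 6 pairs of arrays.

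Of the sort markers, Cd34 separated all 3 fractions, and Cdh3 separated HG from bulge but overlapped between HG and total keratinocytes. Cd34, the surface marker of the bulge gate, lay between 14.42 and 14.79 (log2) on the 4 bulge arrays, between 7.65 and 8.69 on the 4 HG arrays and between 10.03 and 11.30 in total keratinocytes. Cdh3, which encodes P-cadherin, lay between 9.22 and 10.61 in HG, between 8.02 and 9.10 in bulge and between 9.33 and 10.07 in total keratinocytes. These differences follow from the sort. Xist lay between 14.14 and 15.60 on all 12 arrays and the Y-linked genes of the sex check list at or below 5.84, and erythroid markers averaged between 4.94 and 5.84 per array, near the floor of 4.37.

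**Figure D1:**
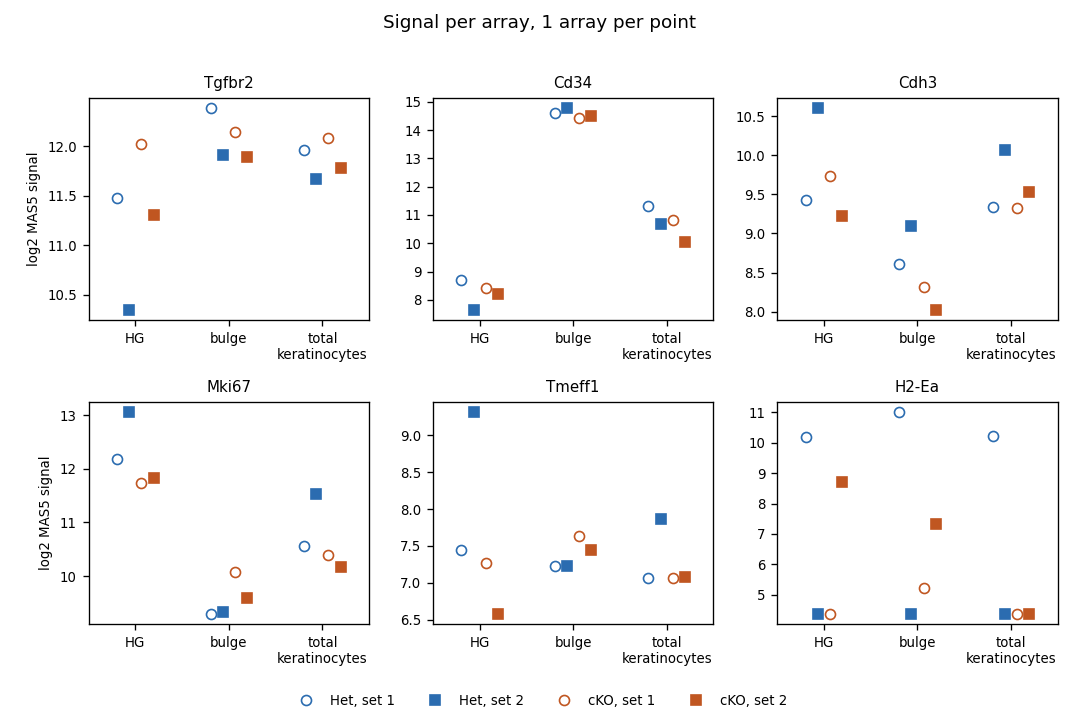
Log2 MAS5 signal (y axis) of Tgfbr2, Cd34, Cdh3, Mki67, Tmeff1 and H2-Ea by fraction (x axis), with 1 point per array, Het in blue, cKO in orange, set 1 as open circles and set 2 as filled squares. Cd34 lies between 14.42 and 14.79 on the bulge arrays and at or below 11.30 on the other 8, and H2-Ea lies at the floor on all 3 Het arrays of set 2.

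The comparison of HG with bulge asked how the 2 stem cell compartments of the same follicle differ, whatever the genotype and set. The HG fraction carried more transcripts of cell division, of the Hedgehog ligand Shh and of the Wnt effector Lef1. The bulge fraction carried more transcripts of the stem cell transcription factors Sox9 and Nfatc1, of Bmp6 and of the BMP targets Id1 and Id2. The BMP response genes Msx2 and Gata3 were higher in HG. Fibroblast genes were higher in the bulge fraction and melanocyte genes higher in HG, so these differences cannot be assigned to the stem cells alone. Of 12589 genes tested with limma on 8 arrays, 1063 rose and 1351 fell in HG relative to bulge at an adjusted p under 0.05, with the genotype-by-set condition as a block of 4 levels. The count of 2414 became 1201 without the 2 arrays of Het set 1, 1413 without those of cKO set 1 and 1304 without those of cKO set 2.

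Among the genes with the largest rise in HG were the neuropeptide gene Grp, by 4.29 on the log2 scale (SE 0.42, adjusted p = 2.12e-04), and Shh, by 4.21 (SE 0.79, adjusted p = 0.0065). Mtmr7 rose by 3.84 (SE 0.25, adjusted p = 2.27e-05), the proton pump gene Atp6v1b1 by 3.73 (SE 0.37, adjusted p = 2.15e-04), the pigment gene Tyrp1 by 3.69 (SE 0.25, adjusted p = 2.44e-05) and Scube3 by 3.66 (SE 0.47, adjusted p = 9.35e-04). The largest falls were the growth factor gene Fgf18 at -7.07 (SE 0.21, adjusted p = 8.33e-07), Krt24 at -5.56 (SE 0.45, adjusted p = 7.39e-05), Wfdc3 at -5.46 (SE 0.29, adjusted p = 7.38e-06), Krt6a at -5.45 (SE 0.24, adjusted p = 3.66e-06) and Angptl7 at -5.33 (SE 0.25, adjusted p = 3.88e-06). Cd34, the gene with the other large fall, is a sort marker. Each of these genes moved the same way in all 4 conditions. Fgf18 and Krt24 are also members of the bulge stem cell list. Fgf18 lay at the floor on 2 of the 4 HG arrays, Scube3 on 3 of the 4 bulge arrays, and Grp and Atp6v1b1 on 1 bulge array each, so these differences are lower bounds. That of Fgf18 ran from -7.81 to -5.51 over the settings.

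Cell cycle genes were higher in HG in nearly the whole list. Of 38 tested, 35 rose and none fell, and 36 rose when adjusted over the list alone, with a median of 1.85 (log2). Mki67 rose by 2.63 (adjusted p = 4.21e-04) and the mitotic kinase gene Bub1 by 2.73 (adjusted p = 3.96e-04), each higher in HG in 4 of 4 conditions. In set 1, where the labels call HG cells quiescent, the list's mean log2 signal was 10.26 in Het HG and 10.06 in cKO HG. In the same order it was 9.73 and 9.68 in total keratinocytes and 8.58 and 8.82 in bulge of set 1. In a rotation test of whether a list moves on balance in 1 direction (limma fry) the adjusted p was 0.0271. It was 0.12 without Het set 1, 0.0903 without cKO set 1 and 0.13 without cKO set 2, with 32, 35 and 34 of the genes risen. A test against all other genes (limma camera) gave an adjusted p of 2.71e-21 with a preset correlation of 0.01, and 0.42 with an estimated correlation. No list passed 0.05 with an estimated correlation in this comparison, where the smallest adjusted p was 0.24. Of 10 CDK inhibitor and growth arrest genes 3 fell, which were Gas1, Cdkn1c and Foxo3, and 4 fell when adjusted over the list alone (median -0.39). That count was 1 without Het set 1 and 2 without cKO set 1 or cKO set 2.

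Stem cell and signalling lists divided the 2 compartments. Of 23 bulge stem cell genes 18 fell in HG and 1 rose (20 and 1 when adjusted over the list alone, median -1.83, fry adjusted p = 0.0038). The sort marker Cd34 is 1 of the 18, and without it 17 of 22 fell (fry adjusted p = 0.0043), a test added after the values were seen. Without cKO set 2, 15 fell and the fry adjusted p was 0.0528. Sox9 changed by -3.22 and Nfatc1 by -3.26, and the gene that rose was the Wnt inhibitor Wif1 (1.32). The fibroblast markers, mostly secreted matrix genes, fell with this list in all 11 cases, so that bulge and fibroblast genes moved together between the 2 fractions. Hair germ and early anagen genes gave 8 risen and 2 fallen of 14 (10 and 2 when adjusted over the list alone, median 1.30, fry adjusted p = 0.0687), the sort marker Cdh3 among the risen, with Lef1 at 2.46 and the BMP target Msx2 at 2.24. Of 15 Wnt response genes 5 rose (6 when adjusted over the list alone, median 0.60), led by Tnfrsf19 at 2.80. Of 7 Hedgehog response genes 4 rose and 1 fell, also when adjusted over the list alone (median 0.86). The ligand gene Shh, a member of this list and of the hair germ list, is 1 of the 4. The fallen gene was Hhip (-3.07), an inhibitor that binds Hedgehog ligands, and Gli1 rose by 0.86.

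BMP and TGF-beta genes changed in both directions. Of 12 BMP response genes 2 rose and 5 fell (2 and 6 when adjusted over the list alone, median -0.71). Id1 changed by -1.31 (adjusted p = 0.0019) and Id2 by -2.76 (adjusted p = 2.16e-05), whereas Msx2 and Gata3 rose. Id3 fell by 0.82 (adjusted p = 0.0183), a call kept in 8 of 13 settings and lost without Het set 1 (-0.73) or cKO set 1 (-0.66). Of 15 BMP receptor, ligand and antagonist genes 4 rose and 4 fell (6 and 5 when adjusted over the list alone), and the list's median of 0.42 and mean of -0.16 differed in sign. Grem1 changed by -4.06 and Bmp6 by -3.17, and the receptor gene Bmpr1b rose by 2.31. Of 16 TGF-beta receptor and Smad genes 6 fell and none rose, also when adjusted over the list alone. Their mean was -0.48 and their median -0.06, and the median became 0.01 without the arrays of Het set 1, where 3 fell, as did 3 without cKO set 2. Tgfbr2 fell by 0.80 (adjusted p = 0.0364), which was called in 7 of 13 settings and not without Het set 1 (-0.76) or cKO set 2 (-0.87), and ran from -1.02 to -0.23 over the settings. Of 18 TGF-beta response genes 2 rose and 4 fell (2 and 6 when adjusted over the list alone, median -0.35), with Ccn2 at -3.12. Fibroblasts also express Ccn2 and the latent TGF-beta binding protein genes Ltbp2 and Ltbp1, which changed by -3.54 and -2.11. Tmeff1 did not pass (0.27, adjusted p = 0.72).

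Genes of other skin cell types differed between the 2 fractions as well. All 11 fibroblast markers fell in HG, also when adjusted over the list alone (median -3.40, fry adjusted p = 0.0025), with Lum at -4.60 and Col1a1 at -3.92. Of 9 melanocyte markers 7 rose and 1 fell (8 and 1 when adjusted over the list alone, median 2.69, fry adjusted p = 0.0025), with Dct at 3.43 and Kit at 2.93. Of 9 sebaceous gland genes 6 fell, also over the list alone (median -0.92). Hair shaft and inner root sheath genes had 3 risen of 16 (median 0.84), which were Krt35, Krt28 and Hoxc13. Of 18 epidermal differentiation genes 2 rose and 1 fell (median 0.14), and of 9 infundibulum and isthmus genes 2 fell (median -0.32). Among 14 dissociation stress genes 3 fell (median -0.58). Single genes fell in the Schwann cell (Pmp22, list median -0.53), wound-activated keratinocyte (Krt6a, -0.36) and immune cell (Lyz2, -0.35) lists. Of 5 dermal papilla markers Rspo3 rose and Lepr fell (1 and 3 when adjusted over the list alone, median -1.01). No gene was called in the endothelial (median -0.95), basal keratinocyte (-0.34) or muscle (-0.29) lists.

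The comparison of HFSCs with total keratinocytes asked what sets the stem cells apart from the mixed epithelium. Genes of epidermal barrier formation and of the upper follicle were lower in HFSCs, whereas Hedgehog targets were higher. Bulge stem cell genes and fibroblast markers were higher from the bulge arrays alone, and melanocyte markers from the HG arrays alone. Of 12749 genes tested with limma on 12 arrays, 1217 rose and 960 fell in HFSCs. The count of 2177 became 850 without cKO set 2, 1017 without the cKO total keratinocyte array of set 2 and 1354 without that of set 1, which carried milk protein transcripts. It was 1143 without Het set 1 and 1173 without cKO set 1.

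The largest rises in HFSCs were A530047J11Rik at 2.74 (SE 0.39, adjusted p = 8.63e-04), the imprinted gene Peg3 at 2.39 (SE 0.23, adjusted p = 1.39e-04), Enox1 at 2.37 (SE 0.31), the membrane peptidase gene Mme at 2.32 (SE 0.23, adjusted p = 1.95e-04), 1700019D03Rik at 2.19 (adjusted p = 0.0017) and Prune2 at 2.14 (adjusted p = 0.0015). The largest falls were the serine protease gene Tmprss4 at -2.87 (SE 0.32, adjusted p = 3.30e-04), the suprabasal keratin gene Krt1 at -2.85 (SE 0.37, adjusted p = 5.70e-04), Gsta2 at -2.81 (SE 0.24, adjusted p = 1.37e-04), Npl at -2.74, Nat8l at -2.71 and the ceramidase gene Acer1 at -2.64 (SE 0.28, adjusted p = 2.65e-04). Prune2 lay at the floor on 1 total keratinocyte array. All 12 genes moved the same way in 8 of 8 pairs of an HFSC and a total keratinocyte array of the same condition. Among the genes followed throughout, Id2 rose by 1.20 (adjusted p = 3.60e-04), higher in 5 of 8 pairs, and Id3 by 0.98 (adjusted p = 0.0026), higher in 8 of 8. Against total keratinocytes Id2 was -0.18 with the HG arrays alone. Id1 (0.53, adjusted p = 0.16), Mki67 (0.22, adjusted p = 0.57), Tmeff1 (0.25, adjusted p = 0.66) and Tgfbr2 (-0.19, adjusted p = 0.50) did not pass.

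Of 19 epidermal differentiation genes 11 fell in HFSCs and none rose, also when adjusted over the list alone (median -0.94, fry adjusted p = 0.0143, adjusted p = 0.40 with an estimated correlation), with Krt2 at -2.35 and the desmoglein gene Dsg1a at -1.98. Infundibulum and isthmus genes gave 5 fallen of 9 (8 when adjusted over the list alone, median -0.85), with Krt79 at -2.22. Without cKO set 2 the fallen genes were 5 and 4 in these lists, without cKO set 1 they were 3 in the infundibulum list, and the fry adjusted p of the epidermal list was 0.10 without cKO set 2, 0.0659 without Het set 1 and 0.0517 without cKO set 1. Of 23 bulge stem cell genes 14 rose, the sort marker Cd34 among them (16 risen and 1 fallen when adjusted over the list alone, median 0.83), led by Lhx2 at 2.03, and all 11 fibroblast markers rose beside them (median 1.25). The count of risen bulge genes was 9 without cKO set 1 and 8 without cKO set 2. With the HG arrays alone against total keratinocytes the medians were -0.13 for the bulge list and -0.58 for the fibroblast list. With the bulge arrays alone they were 1.68 and 2.77. Hedgehog response genes gave 5 risen of 7, also when adjusted over the list alone (median 0.73), with Gli1 at 1.49. They were 3 without Het set 1 or cKO set 1 and 2 without cKO set 2. Melanocyte markers rose beside them in 5 of 9 cases (7 when adjusted over the list alone, median 1.24), with a median of 2.21 in HG alone and -0.35 in bulge alone. Of 39 cell cycle genes 6 fell (median -0.23). Their median was 0.55 in HG alone and -1.24 in bulge alone. TGF-beta receptor and Smad genes gave 4 risen and 1 fallen of 16 (5 and 1 when adjusted over the list alone, and 2 and 1 without cKO set 2), and Cdkn1a, a cell cycle inhibitor and TGF-beta response gene, fell by 1.75. In this comparison the smallest adjusted p with an estimated correlation was 0.40.

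The comparison of set 2 with set 1 in Het HFSCs asked which genes accompany activation. Quiescent Het cells were all in set 1 and activated ones all in set 2, so activation cannot be told apart from other differences between the sets. Total keratinocyte arrays correlated more between genotypes within a set (r = 0.9792 in set 1 and 0.9745 in set 2) than between sets of a genotype (0.9635 in Het and 0.9677 in cKO). The cell division genes Cdc20 and Mcm5 rose, and Lce1m and Lor, genes of terminal epidermal differentiation, fell, and in each of these 2 lists no other member was called. The MHC class II gene H2-Ea was among the genes that fell, while no member of the immune cell list was called. The HG and bulge arrays served as the 2 observations of each condition. With limma 8 genes rose and 81 fell of 12589, and 2117 passed an unadjusted p of 0.05. The count of 89 varied with the arrays used, and was 0 without the Het HG or the Het bulge array of set 1, 264 without the Het HG array of set 2 and 2552 without the Het bulge array of set 2, which was high in dissociation stress genes. Each of these fits leaves 1 array in an arm, whose spread is taken from the other groups. The share of called genes that fell was 91.0%. With all 12 arrays in the fit it was 56.1% of 419 genes, so the size of the excess of fallen genes depended on the arrays used.

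Activated Het HFSCs had higher Gjb2, a gap junction gene (4.15, SE 0.62, adjusted p = 0.0287), Lrat, a retinol enzyme gene (3.13, adjusted p = 0.0371), Tnc (2.03, adjusted p = 0.0371), the kinetochore gene Spc25 (1.78, adjusted p = 0.0269), Nrep (1.70, adjusted p = 0.0350) and the mitotic gene Cdc20 (1.61, adjusted p = 0.0441). H2-Ea was at least 74.2-fold lower (adjusted p = 0.0058), since both set 2 arrays lay at the floor. 2310001H17Rik and Sdcbp2 also lay at the floor on 1 of these arrays each, so their falls are lower bounds, which ran from -4.35 to -1.44 and from -4.06 to -1.56 over the settings. Crct1, a cornified envelope gene, changed by -3.32 (SE 0.31, adjusted p = 0.0051), 2310001H17Rik by -3.46 (adjusted p = 0.0249), Sdcbp2 by -3.35 (adjusted p = 0.0441), 2310050C09Rik by -3.30 (adjusted p = 0.0450) and Lce1m by -3.19 (adjusted p = 0.0287). Each moved the same way in HG and bulge. These calls were kept in 3 to 8 of 11 or 12 settings and lost in 4 to 9, among them the fits without the Het HG or the Het bulge array of set 1. Without these arrays in turn Gjb2 was 4.13 and 4.17, H2-Ea -6.72 and -5.71, Crct1 -3.63 and -3.01, 2310050C09Rik -4.03 and -2.58, and Nrep 1.27 and 2.12. Tgfbr3, the gene of the TGF-beta co-receptor betaglycan, fell by 1.84 (adjusted p = 0.0159).

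All 38 cell cycle genes were positive, with a median of 1.16. Cdc20 and Mcm5 were called, and 29 passed when adjusted over the list alone (fry adjusted p = 0.19, camera adjusted p = 2.29e-19, adjusted p = 0.58 with an estimated correlation). Of 18 epidermal differentiation genes Lce1m and the loricrin gene Lor fell (10 when adjusted over the list alone, median -1.35, fry adjusted p = 0.0085, adjusted p = 0.19 with an estimated correlation). Without the Het HG array of set 1 the fry adjusted p was 0.0654. All 15 immune cell markers were negative beside them (median -1.19), with none called and 1 passing over the list alone. Hair shaft and inner root sheath genes had a median of 2.39 with none called (6 higher and 1 lower when adjusted over the list alone). Gata6 (-2.29) was the infundibulum gene that fell, and Lum (-1.33) the fibroblast marker. Dissociation stress genes moved apart in the 2 fractions, with a median of -0.51 in HG (6 of 14 at least 2-fold lower) and 1.49 in bulge (11 of 14 at least 2-fold higher). Their mean log2 signal was 12.94 on the Het bulge array of set 2 and 11.49 on that of set 1. Over both fractions the median was 0.11, with none called, and -0.73 without the Het bulge array of set 2. Tmeff1 (0.94, adjusted p = 0.49), Mki67 (0.46, adjusted p = 0.61), Id1 (0.36), Id2 (0.42), Id3 (0.96, adjusted p = 0.15) and Tgfbr2 (-0.80, adjusted p = 0.25) did not pass. Quantile normalization moved the median of all genes in this contrast from -0.09 to 0.01, and the stress gene median to -0.07.

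In HG cells alone each condition had 1 array, and no test between arrays was made. Cell cycle, hair shaft, Hedgehog and early anagen genes were higher in activated Het HG than in quiescent Het HG. Genes of the epidermal, basal, infundibular, immune and fibroblast lists were lower on the same array. In Het HG 3300 of 11866 genes (27.8%) differed at least 2-fold between the sets. The corresponding shares were 9.20% between the 2 Het total keratinocyte arrays, 8.02% between the 2 cKO ones, 8.74% between the cKO HG arrays, 11.3% between the Het bulge arrays and 12.3% between the cKO bulge arrays. The total keratinocyte arrays of a genotype also differ in set, so their share is not a level without change. The Het HG array of set 2 also stood apart from the other 3 HG arrays in measures of the array itself. Its median signal was 63.9 (95.6 to 98.8 on the others), 29.0% of its values lay at the floor (22.5% to 23.1%), its actin 3' to 5' log2 ratio was 2.02 (2.44 to 2.68) and its 18S rRNA control 14.46 (11.72 to 12.79). Of the 3300 genes 1049 were higher and 2251 lower (68.2% lower). With quantile normalization they were 1424 and 1441. That scaling also moved the median of all genes from -0.14 to 0.04. Of the 24 lists, the CDK inhibitor, muscle and Wnt response medians changed sign with it.

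The largest increases in activated Het HG were in genes of the hair shaft and its sheath, which were also higher in set 2 of other fractions. The median of the hair shaft list was 4.47 between the Het total keratinocyte arrays (14 of 16 genes at least 2-fold higher), 2.54 between the cKO ones, 0.56 between the Het bulge and 1.88 between the cKO bulge arrays. For cell cycle genes it was 1.01 (21 of 39), 0.20, 0.67 and 0.09 in the same order. Krtap8-1 was higher by 8.08 (log2) and Krt25 by 7.06, and Krtap11-1 was at least 181-fold, Krtap7-1 at least 128-fold, Krtap15 at least 78.3-fold and Krt75 at least 64.1-fold higher. H2-Ea was at least 55.5-fold and Zbtb7c at least 17.5-fold lower. Rnase2b (-5.02), Gm13306 (-4.27), the immediate early gene Fosb (-4.21) and C030013C21Rik (-4.09) were the other largest decreases. In cKO HG, hair keratin genes again led, with Krtap8-1 at least 68.1-fold, Krt25 at least 34.1-fold, H2-Ea at least 20.1-fold, Gm10229 at least 19.2-fold and Krtap22-2 at least 15.4-fold higher, and Krt33a higher by 4.15. Gt(ROSA)26Sor (-4.26), Rfx2 (-3.63), Gga1 (-3.43), Fam43a (-3.24), Dock6 (at least 14.1-fold lower) and the milk protein gene Csn2 (at least 10.7-fold lower) were lowest there.

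Each list's median was set against 10000 random lists matched in size and expression, which compares genes within 1 pair of arrays and ignores the correlation between them. The hair shaft and inner root sheath median was 4.84 in Het HG (15 of 17 at least 2-fold higher) and 2.19 in cKO HG (12 of 16), at percentile 100 in both. Krt35 was higher by 5.42 in Het and 2.29 in cKO. Between the bulge arrays the hair shaft median was instead lower in Het (0.56) than in cKO (1.88). For cell cycle genes the medians were 1.57 in Het HG (32 of 39 at least 2-fold higher) and 0.33 in cKO HG (1 of 38), also at percentile 100 in both. Mki67 went from 12.18 to 13.06 in Het and from 11.73 to 11.82 in cKO. BMP response genes had medians of 1.38 and 0.94, with Dlx3 at 5.49 and 2.36 and Msx1 at 3.98 and 1.06. Id1 was higher by 0.67 in Het and 1.01 in cKO, Id2 by 0.69 and 0.29, and Id3 by 1.31 and 1.21. Early anagen genes had medians of 1.01 and 0.23, with Shh at 2.65 and 0.22 and Lef1 at 2.25 and 0.23. Hedgehog response genes had medians of 1.08 and 0.29. Tmeff1, a target of TGF-beta signalling, went from 7.44 to 9.32 in Het and from 7.27 to 6.58 in cKO. A second probe set of Tmeff1, looked at after the values were seen, gave 5.65 and 6.69 in Het but 5.78 in both sets of cKO, so the decrease in cKO was seen on 1 of the 2 probe sets.

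Several lists had larger decreases in Het HG than in cKO HG. Epidermal differentiation genes had medians of -1.69 in Het and -0.66 in cKO, basal keratinocyte genes -1.36 and -0.44, and the fibroblast markers -1.13 and -0.67. Infundibulum and isthmus genes had medians of -2.40 in Het and -0.42 in cKO, with Cst6 at -3.84 in Het and 0.59 in cKO. Immune cell markers had a median of -1.88 in Het, where 14 of 15 were at least 2-fold lower. In cKO that median was -0.06, and 0.05 with quantile normalization. Wnt response genes had medians of -0.05 in Het, which was 0.21 with quantile normalization, and -0.55 in cKO. Whether the set difference itself differed between genotypes was tested only in the fit of HG and bulge together.

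**Figure D2:**
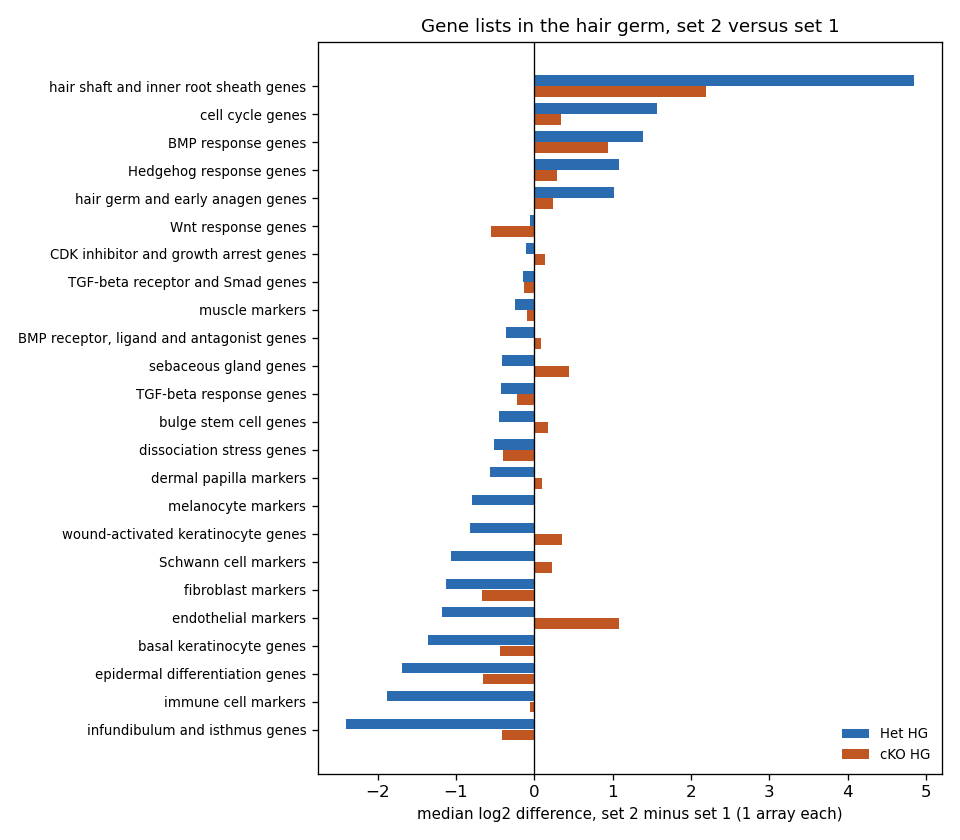
Median log2 difference between set 2 and set 1 (x axis) of 24 gene lists (y axis) in Het HG (blue) and cKO HG (orange), from 1 array per condition. The bars reach 4.84 and 2.19 for hair shaft genes and 1.57 and 0.33 for cell cycle genes, and the CDK inhibitor, muscle and Wnt response bars of Het and the immune and Schwann cell bars of cKO change sign with quantile normalization.

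In cKO HFSCs the labels describe cells that stayed quiescent in set 2. No gene passed between the sets in the limma fit of HG and bulge (777 passed an unadjusted p of 0.05, smallest adjusted p = 0.24). On simulated data this contrast recovered 17.9% of 2-fold and 82.1% of 4-fold changes, so most changes of 2-fold would be missed. Hair shaft genes had a median of 2.40, close to their median in Het, with 15 of 16 positive and 1 passing over the list alone. Cell cycle genes had a median of 0.21, against 1.16 in Het. Epidermal differentiation genes had a median of -0.65 (3 passing over the list alone), and all 11 fibroblast markers were negative (median -0.62, 4 passing over the list alone). The smallest fry adjusted p among these lists was 0.0626. Tmeff1 (-0.44, adjusted p = 0.92), Mki67 (-0.20, adjusted p = 0.95), Id1 (0.59, adjusted p = 0.80), Id2 (0.22, adjusted p = 0.89), Id3 (0.77, adjusted p = 0.79) and Tgfbr2 (-0.48, adjusted p = 0.82) did not pass.

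The interaction tested whether the set difference itself differed between genotypes, and 1 gene passed with limma, H2-Ea (9.42, SE 0.87, adjusted p = 0.0192, a lower bound since low values lay at the floor), while 917 passed an unadjusted p of 0.05. On the probe set used, H2-Ea was higher in set 1 than in set 2 in both Het fractions and lower in both cKO fractions. On a second probe set of H2-Ea, looked at after the result was seen, cKO bulge was 4.73 in set 1 and 4.72 in set 2, near the floor, so the cKO part was seen on both probe sets only in HG (5.28 and 8.56 on the second). It was called in 5 of 16 settings, and the count was 994 without the Het bulge array of set 2, where stress genes were high, 77 without the Het HG array of set 2, 1 without the cKO bulge array of set 2 and 0 without any of the other 5 arrays. The cell cycle median was -0.76, with 37 of 38 genes negative (fry adjusted p = 0.68, camera adjusted p = 3.45e-11, adjusted p = 0.82 with an estimated correlation). A different cell cycle response in cKO was thus not shown by the tests that allow for correlation between genes. Nor can these tests exclude one. On simulated data this contrast recovered 2.99% of single genes changed 2-fold. The fit also has no term for a set difference that itself differs between HG and bulge, so such a difference counts as error. Tmeff1 (-1.37, adjusted p = 0.77), Mki67 (-0.66, adjusted p = 0.81), Id1 (0.22, adjusted p = 0.92), Id2 (-0.20, adjusted p = 0.92), Id3 (-0.19, adjusted p = 0.93) and Tgfbr2 (0.32, adjusted p = 0.89) did not pass.

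Within set 2 the comparison of cKO with Het set aberrantly quiescent against activated HFSCs. Zbtb16 and Fam107a were among the genes higher in cKO, and a mitotic kinesin gene was lower. With limma 32 genes rose and 1 fell of 12589, and 2226 passed an unadjusted p of 0.05. The count of 33 was 0 without the cKO HG or the cKO bulge array of set 2, 281 without the Het HG array (202 higher and 79 lower) and 2438 without the Het bulge array of set 2 (1458 higher and 980 lower). With all 12 arrays in the fit 6 genes were higher and 3 lower, so the size of the excess of higher genes depended on the arrays used. Fam107a rose by 3.17 (adjusted p = 0.0293), the guidance cue gene Sema3d by 3.12 (SE 0.31, adjusted p = 0.0125), the transcription factor gene Zbtb16 by 2.87 (adjusted p = 0.0293), the noncoding RNA Neat1 by 2.86 (SE 0.28, adjusted p = 0.0125), Il22ra2 by 2.69 (adjusted p = 0.0125) and Clca3a1 by 2.56 (adjusted p = 0.0409). Kif22 fell by 1.48 (adjusted p = 0.0370). Each moved the same way in HG and bulge, and these calls were kept in 4 to 6 of 11 or 12 settings and lost in the other 6 to 8. Tgfbr3 rose by 1.81 (adjusted p = 0.0293). In set 1, a contrast chosen after the values had been seen, no gene differed between the genotypes (261 passed an unadjusted p of 0.05, smallest adjusted p = 0.0640). There Tmeff1 was 0.11, Mki67 0.17, Id1 -0.52, Id2 -0.30, Id3 -0.37 and Tgfbr2 0.15 (adjusted p = 1.0 for each).

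All 38 cell cycle genes had negative estimates in cKO HFSCs of set 2, with none called and 13 passing over the list alone (median -0.81, fry adjusted p = 0.35, camera adjusted p = 4.56e-12, adjusted p = 0.75 with an estimated correlation). Endothelial markers were positive in 7 of 7 cases beside them (median 1.08, 3 passing over the list alone), led by Cldn5 at 2.85. Sebaceous gland genes had a median of 1.06 (5 passing over the list alone), with Pparg at 2.89, and epidermal differentiation genes 0.77 (3 passing over the list alone). Tmeff1 (-1.26, adjusted p = 0.34), Mki67 (-0.49, adjusted p = 0.56), Id1 (-0.30), Id2 (-0.49), Id3 (-0.56) and Tgfbr2 (0.47, adjusted p = 0.47) did not pass. With quantile normalization the median of all genes moved from 0.04 to -0.07. The HG arrays of set 2 alone differed at least 2-fold in 2993 of 11804 genes (25.4%), again with the Het HG array of lowest median signal, against 6.65% between the HG arrays of set 1. On these 2 arrays the medians of cKO minus Het were -1.47 for cell cycle genes, -2.87 for hair shaft genes, 2.17 for immune cell markers and 1.23 for basal keratinocyte genes. Aldh1a3 was at least 84.4-fold lower in cKO, and Kif26a (-4.66), Padi3 (-4.61), Syt7 (-4.45), Krt35 (-4.20) and Krt25 (-4.17) followed. Gm13306 (4.35), Slc4a8 (3.78), Depp1 (3.71), H2-Ea (at least 20.1-fold), Sdcbp2 (at least 19.6-fold) and Apol7a (at least 14.6-fold) were higher.

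**Figure D3:**
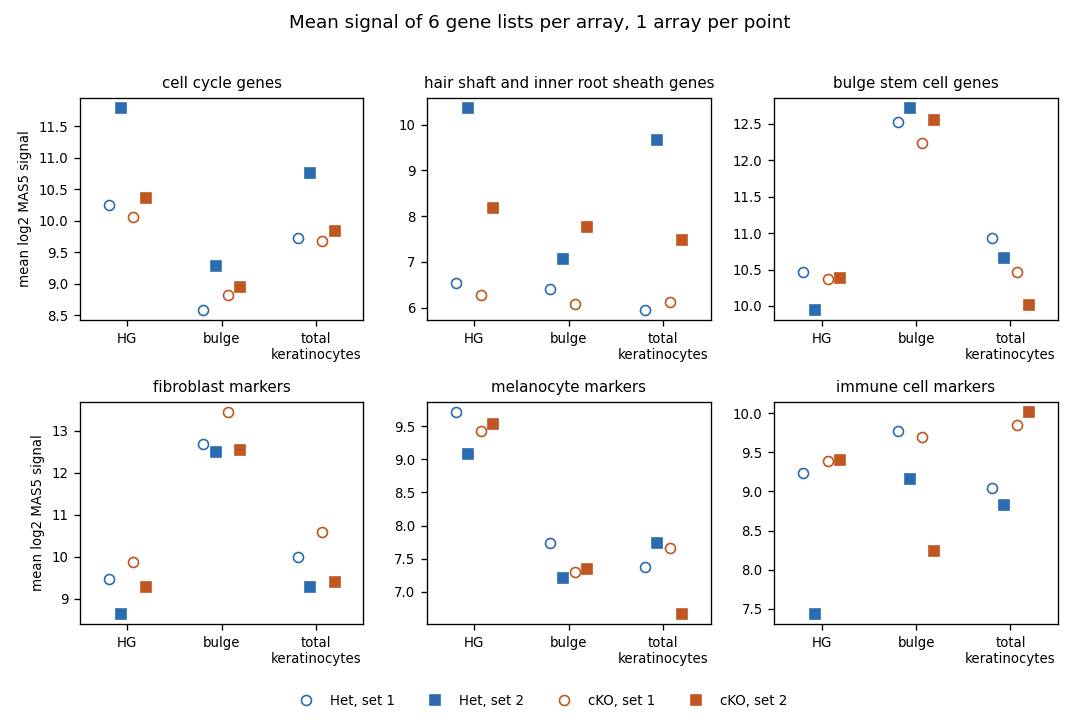
Mean log2 MAS5 signal (y axis) of the cell cycle, hair shaft, bulge stem cell, fibroblast, melanocyte and immune lists by fraction (x axis), with 1 point per array, Het in blue, cKO in orange, set 1 as open circles and set 2 as filled squares. Among the HG arrays activated Het HG has the highest cell cycle mean (11.79, the others at or below 10.35) and the lowest immune mean (7.44, the others at or above 9.23).

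The comparison of cKO with Het over all 3 fractions asked for a genotype effect common to fractions and sets. No gene passed. The cell cycle, hair shaft and immune lists leaned to 1 side on average but not in every fraction and set, whereas the mean of the fibroblast markers was higher in cKO in 6 of 6 pairs of arrays. With limma 0 of 12749 genes differed (1099 at an unadjusted p under 0.05, smallest adjusted p = 0.19), in a design that recovered 71.6% of 2-fold changes simulated with independent arrays. With the genotype-by-set condition as a random block 6 genes passed, 4 of them higher in cKO. Deviations from the fraction mean correlated across genes between fractions of 1 condition with a median r of 0.23, and with -0.05 between conditions. Cell cycle genes had negative estimates in 37 of 39 cases (7 passing over the list alone, median -0.44, fry adjusted p = 0.34, camera adjusted p = 1.40e-11, adjusted p = 0.43 with an estimated correlation). Estimates were also negative for 15 of 17 hair shaft genes (median -0.80, fry adjusted p = 0.41) and 10 of 12 BMP response genes (median -0.42, fry adjusted p = 0.27). The cell cycle difference lay mostly in set 2, where the mean log2 signals of the list in cKO and Het were 10.35 and 11.79 in HG, 8.94 and 9.28 in bulge and 9.83 and 10.76 in total keratinocytes. In set 1 they were 10.06 and 10.26, 8.82 and 8.58, and 9.68 and 9.73. Hair shaft means were higher in cKO in bulge of set 2 (7.75 and 7.07) and in total keratinocytes of set 1 (6.12 and 5.95). Immune cell markers had positive estimates in 14 of 15 cases (median 0.58, fry adjusted p = 0.41), but their mean was lower in cKO bulge, with 9.70 and 9.77 in set 1 and 8.24 and 9.16 in set 2. Fibroblast markers had positive estimates in 10 of 11 cases (median 0.45, 4 passing over the list alone, fry adjusted p = 0.20). Tmeff1 (-0.51, adjusted p = 0.69), Mki67 (-0.36, adjusted p = 0.69), Id1 (0.01), Id2 (-0.36) and Id3 (-0.24) did not pass.

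Total keratinocytes were the fraction with 2 arrays per genotype. The cKO array of set 1 carried milk protein transcripts and that of set 2 high dissociation stress genes (mean 13.58, with 12.94 on the Het bulge array of set 2 and 10.40 to 11.90 on the other 10). With limma 0 of 11121 genes differed (247 at an unadjusted p under 0.05), and the count was 59 without the cKO array of set 1, 10 without the cKO array of set 2 and 8 without the Het array of set 1. All 15 immune cell markers had positive estimates in cKO (median 1.00), with none called and 10 passing over the list alone, led by H2-Ab1 at 1.59 and the Langerhans cell gene Cd207 at 1.54 (fry adjusted p = 0.37, camera adjusted p = 3.88e-21, adjusted p = 0.67 with an estimated correlation). Estimates were negative for 36 of 38 cell cycle genes (median -0.54), 6 of 6 Hedgehog response genes (median -0.73) and 7 of 7 melanocyte markers (median -0.54), and positive for 8 of 8 sebaceous gland genes (median 0.63). In these 4 lists no gene was called or passed over the list alone. Each had a fry adjusted p of 0.84 and an adjusted p of 0.67 with an estimated correlation, so no difference was shown. The mean of the melanocyte list in cKO and Het was 7.67 and 7.38 in set 1 and 6.67 and 7.74 in set 2, so its direction differed between the sets. Tmeff1 (-0.39), Mki67 (-0.77), Id1 (0.84), Id2 (-0.28), Id3 (0.21) and Tgfbr2 (0.12) did not pass either (adjusted p = 1.0 for each).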

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

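The RNA quality test and the test of the Het part of the H2-Ea pattern were chosen after the result was seen, and the other tests before. The second probe set of H2-Ea was also looked at afterwards.

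Each fraction's 4 arrays were searched for an array far from the other 3, in 102 groups of 4, and 8 gave one, where chance gives about 1 in 20. The 4 arrays of a fraction span 4 conditions, so such an array is not a failed replicate. Het HG of set 2 had the highest mean log2 signal of cell cycle genes (11.79, the others 10.06 to 10.35) and Hedgehog response genes (10.54, the others 9.45 to 9.62). It had the lowest mean of dermal papilla (6.02, the others 6.42 to 6.49), immune cell (7.44, the others 9.23 to 9.40) and Schwann cell markers (7.60, the others 8.64 to 8.86). Het bulge of set 2 had the lowest mean of sebaceous gland genes (9.16, the others 10.24 to 10.42). Het total keratinocytes of set 2 had the highest mean of cell cycle genes (10.76, the others 9.68 to 9.83) and the highest Tmeff1 (7.86, the others 7.06 to 7.08).

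Probe sets without a single gene symbol were outside the comparisons. Of 4188 tested with limma, 31 differed between the sets in Het HFSCs, 1 of them higher. Between the genotypes in HFSCs of set 2, 201 differed, 194 of them higher in cKO. Of 12589 genes, 89 and 33 were called in the same contrasts. No alternative settings were run for these probe sets, so how far the 31 and 201 depend on the arrays used is not known.

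The set difference of H2-Ea differed between the genotypes (interaction 9.42), since in Het its log2 signal was 10.17 in HG, 11.01 in bulge and 10.21 in total keratinocytes of set 1, and all 3 arrays of set 2 lay at the floor. In cKO this probe set lay at the floor in HG and total keratinocytes of set 1 with 5.24 in bulge, and was 8.70 in HG, 7.32 in bulge and at the floor in total keratinocytes of set 2, whereas a second probe set gave 5.28 in HG and 4.73 in bulge of set 1 and 8.56 and 4.72 in set 2, which leaves the cKO bulge value in doubt. More antigen-presenting cells would move H2-Ab1 as well, but its interaction was 0.0178 of that of H2-Ea, which argues against them as the whole cause. The interactions of Cd207 and Ptprc had the same sign as that of H2-Ea, at 1.49 (SE 0.72) and 1.04 (SE 0.79), but did not pass. In cKO bulge both were lower in set 2 than in set 1 (Cd207 7.05 and 7.62, Ptprc 8.20 and 9.66), unlike H2-Ea on the probe set used. An MHC haplotype of the mixed strain background without H2-Ea expression predicted the same states in total keratinocytes of every set, and the gap there was 0, which argues against it for the pattern as a whole if the fractions of a set shared mice, which the labels do not say. For Het alone the total keratinocytes of set 1 exceeded those of set 2 by 5.84, so a haplotype may account for the Het part. Activation remains an untested alternative there. The cKO HG array of set 1, which the labels call quiescent, also lay at the floor, so such a value is not particular to activated cells.

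All 11 fibroblast markers, none of which is in another list, were higher in bulge than in HG. A second list of 20 fibroblast genes, none of them in another list, had a median of 2.33 (quartiles 1.63 and 2.72) on the log2 scale, with 17 of 19 higher in bulge and none lower. Quantile normalization left the first list's median at 3.26, which argues against array scaling. Fibroblasts in the bulge fraction are therefore a candidate source, although the sort by YFP, P-cadherin and CD34 was meant to remove cells without the epithelial label, and the levels were high (Col1a2 15.11 to 16.31 in bulge and 11.01 to 13.09 in HG, Col3a1 15.13 to 16.16 and 11.01 to 12.65). In the second list the transcription factor genes Twist1 (2.71), Twist2 (2.44) and Prrx1 (2.24) and the receptor gene Pdgfrb (2.49) were higher in bulge. None of these encodes matrix, which argues against higher matrix expression alone, although the surface protein gene Thy1 (0.44) did not pass. How many of the fibroblast genes bulge cells express themselves was not measured, and their expression by bulge cells stays open as the biological alternative.

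Of the genes that differed in activated Het HFSCs, 91.0% were lower in the fit of the HG and bulge arrays. With all 12 arrays in the fit the share was 56.1% of 419 genes. The size of the excess of lower genes thus depended on the arrays used. With quantile normalization the share in the fit of the HG and bulge arrays was 85.9%. This argues against array scaling as the whole cause among the genes called in that fit. On the Het HG arrays alone, the share of lower genes among those changed at least 2-fold went from 68.2% to 50.3%. Scaling therefore stays open there. For RNA quality, the actin 3' to 5' log2 ratio of 1 of the 2 activated Het arrays lay within the range of the other 6 HFSC arrays (Het bulge 2.61 and Het HG 2.02, the others 2.40 to 2.99), which leaves the explanation undecided. The log2 signal of an 18S rRNA control probe set was 14.46 and 14.93 on these 2 arrays and 11.72 to 13.86 on the other 6, so a difference in RNA composition may contribute. Activation itself, which the labels give for these arrays, remains an untested biological alternative.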

How the results depend on the processing

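The 6 alternatives that leave out arrays in doubt, or the HG or bulge arrays of the comparison with total keratinocytes, were chosen after the values were seen, as were the lists without the sort markers and the split test within conditions, and the others before. Of the gene counts, 73 stayed within 1.5 times the reported value and 56 did not. The 73 include many cases in which a reported count of 0 stayed 0. For the set contrast in Het HFSCs, the interaction and cKO against Het in set 2, most alternatives moved the count. Of the named genes' values, 1210 kept direction and call, 154 lost the call, 23 gained it, 45 without a call moved and 3 reversed. Of the list medians, 2215 were kept, 80 lost and 64 gained the test, 183 moved and 6 reversed. Of the single-array values 416 were kept and 87 moved. Among 3983 values of named genes and lists, 228 not called under either setting changed sign and are counted as moved. The cause was not tested unless a reason is given.

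For HG against bulge the count of 2414 was 1510 with the 2-fold minimum, 648 without the filter, where more genes are tested, and 1586 without the trend. Leaving out 1 condition gave 1201 to 2807. The median of TGF-beta receptor and Smad genes became 0.01 without Het set 1. For HFSCs against total keratinocytes the count of 2177 was 1042 with the 2-fold minimum, 1260 without the filter, 1436 with no replicate block and 850 to 2806 without 1 condition. It was 1017 without the cKO total keratinocyte array of set 2, 1354 without that of set 1 and 1429 with the HG arrays alone. With HG alone, Cd34 was -2.47, Id2 -0.18, the bulge list -0.13 and the fibroblast list -0.58. With bulge alone, Mki67 was -1.09 and the melanocyte list -0.35.

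For cKO against Het over all fractions the count was 6 with condition as a random block and 0 under every other alternative run. In total keratinocytes it was 0 with the replicate block, in which the arrays share only a set number, and 0 to 59 without 1 array. For set 2 against set 1 in Het HFSCs the count of 89 was 26 with the floor at the pooled median, 0 without the filter, 20 with the mean of all probe sets, 0 without the trend, 419 on all 12 arrays and 0 to 2552 without 1 array. The stress list became -0.73 without the Het bulge array of set 2, and 0.37 in the interaction, where leaving out 1 array gave -1.82 to 0.37. In cKO HFSCs the count was 7 on all 12 arrays and otherwise 0. The interaction's 1 gene became 0 without the floor, with the floor at the pooled median, without the filter, with the 75th percentile filter, with the mean of all probe sets and without the trend. It was 2 on all 12 arrays and 0 to 994 without 1 array. For cKO against Het in set 2 the count of 33 was 7 with the floor at the pooled median, 0 without the filter, with the mean of all probe sets and without the trend, 9 on all 12 arrays and 0 to 2438 without 1 array.

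For Het HG between the sets, the 3300 genes became 1697 with the 75th percentile filter, under which fewer genes are counted. For cKO HG the 1054 genes became 527 with the floor at the pooled median, 2358 without the filter and 226 with the 75th percentile filter. Low signal limits these values, since 21.2% to 29.0% of probe sets lay at the floor on each array.

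Other splits of the arrays were fitted in the same way. For HG against bulge 32 of 35 splits could be fitted, since the other 3 coincide with the block. The real one gave 2414 genes and the highest other of those fitted gave 0. Of these, 8 keep 1 array of each condition on each side, with the same highest other of 0, which is too few for a share under 0.05. For HFSCs against total keratinocytes 1 of 100 drawn splits, the real one, gave 2177 genes and the highest other gave 1. Among 92 splits drawn from those that relabel fractions within conditions, a test chosen afterwards, the real one was also the only one as large. The highest other there gave 2138 and set the bulge arrays apart from the rest, which is a structure of the samples. A count near the real one thus came from setting the bulge arrays apart. The splits therefore do not tie the count to HFSCs against total keratinocytes. For cKO against Het over all fractions the real count was 0, so all 96 of the 100 drawn splits that could be fitted gave as many and the splits decide nothing. The highest other gave 571, which points to a structure of the samples, since with the block in the fit it amounts to cKO against Het in HG and bulge of set 2.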

Other observations

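The genes in this part were all picked after their values were seen, and no explanation was weighed. The cKO total keratinocyte array of set 1 carried milk protein transcripts, with log2 signals of 13.46 for Csn2, 12.37 for Wap, 12.35 for Csn1s1, 12.44 for Csn1s2a, 11.04 for Csn1s2b and 11.55 for Csn3. On cKO HG of set 1 they were 7.80 for Csn2, 7.47 for Csn1s1, 6.70 for Csn1s2a, 6.56 for Csn1s2b and 6.18 for Wap. The cKO bulge array of set 1 had 6.29 for Csn2, 6.67 for Csn1s1 and 6.02 for Wap, and Het HG of set 1 had 6.22 for Wap. The remaining values of these genes lay between 4.37 and 5.89.

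Gt(ROSA)26Sor, the transcript of the locus that carries the YFP marker, had log2 signals of 9.58 in HG, 8.89 in bulge and 9.24 in total keratinocytes of cKO set 1. On the other 9 arrays it lay between 5.32 and 6.94.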
